A study of Arabidopsis thaliana with 5 samples.

How the data were processed

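RNA from the secondary meristem of clipped Arabidopsis thaliana plants was measured on 5 arrays, 3 of Columbia and 2 of Landsberg erecta. Per the labels' protocols, seeds were kept in the cold for 3 days, plants were grown in 3 inch pots in a greenhouse under 16 h of light and 8 h of darkness, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 2 ug of it for Affymetrix arrays. The deposited values are on the log2 scale, as their range shows (2.15 to 15.1, with array medians from 5.44 to 5.50). How the authors corrected the background, normalized and summarized the probe sets to make these log2 values is not given in the sources used here, so their scale and centring beyond this stay unknown. In the deposited table, 6318 probe sets (27.8%) held 1 value on all 5 arrays, 4924 of them at the shared minimum, and 5097 of the 12106 probe sets with a mean above 5 had the same value on at least 2 arrays. Such ties may make the spread of a probe set look smaller than it is, and they leave differences near the minimum unmeasured. The labels call the arrays biological replicates.

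The table held 22810 probe sets, of which 64 controls were left out of the tests. Gene names came from the platform annotation, updated by gene identifier to RefSeq names of assembly TAIR10.1. It listed 14016 probe sets: 13513 with 1 gene (13356 genes), of which 13436 matched a RefSeq gene and 77 kept the annotation's name, and 503 with several genes, from which no gene was named. The other 8794, controls included, are unnamed here. No coordinates were used.

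Differences were coded as Columbia minus Landsberg erecta and fitted for each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 5 arrays, no covariate, no filter), with Benjamini-Hochberg adjustment over 22746 probe sets and a threshold of 0.05. The prior had 0.359 degrees of freedom beside 3 residual ones, so that the fit borrowed little spread between probe sets. A list of 25 gene sets with 569 loci was fixed before the data were examined, and so were the tests, the alternatives and the rule for named genes. Only 85 of these loci had a named probe set, so most lists are read from few members. Lists were tested with camera (preset correlation 0.01, the probe set with the highest mean for each gene, adjusted over the 21 lists with a measured gene), and beside it with camera at an estimated correlation and with fry. Named genes were the 10 with the largest difference per direction among those past the threshold without overlap between the ecotypes, or, where none passed, the 3 with the smallest p; from each list, up to 2 members per direction past the threshold or, with none, the member with the smallest p; and G6PD1, ERECTA, FLC, ESP and AOP3. Lists of circadian clock, cold response and heat shock genes and of 69 plastid-encoded genes were added after the data were seen, as were 10000 random lists matched in mean expression. Control ratios and array medians were compared by exact permutation over the 10 splits of 5 arrays into 3 and 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

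The fit was tested on simulated data for this comparison, with 22746 probe sets that kept their means and spreads. With 200 probe sets changed, limma recovered 18.8% of 2-fold and 45.5% of 4-fold changes on average over 10 runs, with 5.3 false calls per run; with 2000 changed, it recovered 56.4% and 84.7%, with 75.7 false calls per run. Absence of overlap together with means at least 2-fold apart found 49.1% of 2-fold and 98.8% of 4-fold changes when 200 were changed, with 72 false finds per run (70.1 with 2000 changed). The deposited values gave 8 by this rule in all, so the simulation does not match these arrays closely and its rates are rough. In a simulation of the set test on 13356 genes, a list of 24 genes shifted by 0.5 was called in 20 of 20 runs, and 3 of 200 lists without a shift were called. Its genes were drawn independently. The measured lists were mostly shorter and their members moved together: photosynthesis had 6 genes with an estimated correlation of 0.25, anthocyanin 5 with 0.83. The simulation therefore does not give the rate of false calls for these lists.

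Alternatives were quantile normalization, equal array medians, leaving out the probe sets below the 25th or 50th percentile of the mean, eBayes with a trend or robust, array weights, each array left out in turn, the replicate number as a block, leaving out probe sets that can bind several genes, a minimum difference of 2-fold, an unadjusted p under 0.05, an adjusted p under 0.10, and for lists the other set tests and the mean of all probe sets of a gene. Added after the data were seen were fits without probe sets at 1 value on all arrays, without plastid-encoded genes, camera with an estimated correlation under equal array medians, the replicate block and each left-out array, and lists with at least 3 measured genes.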

Results

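Expression was measured on 5 Affymetrix arrays of the secondary meristem of Arabidopsis thaliana plants clipped at bolting, a treatment that imitates browsing by a mammal. The plants belonged to 2 ecotypes, Columbia (3 arrays) and Landsberg erecta (2 arrays), which the series' design text says were picked because they compensate differently for such damage. Material was collected on the day after clipping. All 5 arrays came from clipped plants, so the comparison made here was between clipped Columbia and clipped Landsberg erecta, and the response to clipping itself was not analysed here. Each array held 22746 probe sets besides the controls. The median log2 value was 5.44 and 5.50 on Landsberg erecta replicates 1 and 2, and 5.44, 5.46 and 5.45 on Columbia replicates 1 to 3. The lowest log2 value, 2.15, was shared by all arrays and held 24.4% to 25.2% of the probe sets of each, so these values carry no order. The number of arrays limits the precision of every value below.

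No difference between the clipped meristems of the ecotypes passed the threshold for a single probe set. No probe set was called higher in Columbia (0) or higher in Landsberg erecta (0) by limma with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.165. At an unadjusted p under 0.05, limma gave 265 probe sets higher in Columbia and 141 higher in Landsberg erecta, together 1.78% of those tested. Among the 16428 probe sets that varied between arrays, the median absolute difference of the ecotype means was 0.10 on the log2 scale, and 99% of the differences were below 0.62. For 14093 of them (85.8%) the 95% confidence interval of the difference excluded a 2-fold change in either direction, while for 2335 it did not. Ties between arrays may make such intervals too narrow, and smaller differences are not excluded. For 8 probe sets, 4 in each direction, the ecotypes did not overlap and their means lay at least 2-fold apart. None of the 8 passed the adjusted test. The simulated arrays gave 72 by the same rule among unchanged probe sets. That simulation drew independent normal values and does not match these arrays closely, so 72 is not a chance level for the 8. Values of the ecotypes did not overlap for 1556 probe sets, 9.47% of those that varied, against 10.1% to 13.9% in the 9 other splits of the arrays into 3 and 2. The counts rested on both Landsberg erecta arrays: without replicate 1, limma called 356 probe sets higher in Columbia and 658 higher in Landsberg erecta, and without replicate 2 it called 279 and 656. Of these calls, 650 and 703, respectively, were probe sets whose 3 Columbia values were identical, and the lone remaining array was assumed to vary like the Columbia arrays.

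**Figure D1:**
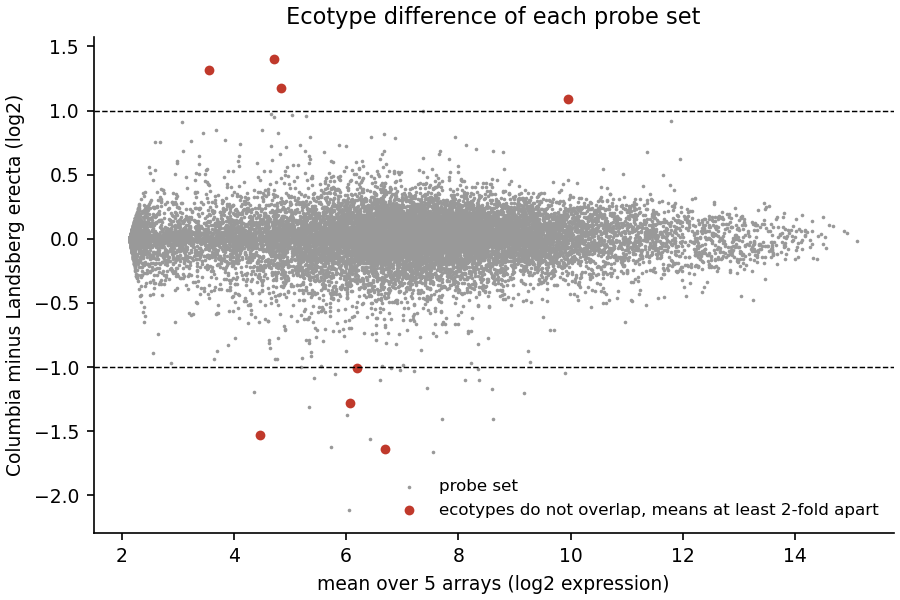
Difference of the ecotype means (Columbia minus Landsberg erecta, log2) against the mean over 5 arrays (log2 expression), with a point for each probe set and dashed lines at a 2-fold difference. The 8 red points are the probe sets whose ecotypes did not overlap and whose means lay at least 2-fold apart.

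The genes with the smallest unadjusted p differed by less than 2-fold and did not pass the adjusted test. ATCES1, which encodes an alkaline ceramidase, had a log2 value of 6.08 ± 0.04 (SD, n = 3) in Columbia and 5.62 ± 0.01 (SD, n = 2) in Landsberg erecta, a difference of 0.46 with a 95% interval from 0.38 to 0.54 (limma adjusted p = 0.740). AT1G73380 had 4.11 ± 0.03 (SD, n = 3) and 3.71 ± 0.01 (SD, n = 2), and AT2G36360 had 6.91 ± 0.02 (SD, n = 3) and 6.55 ± 0.04 (SD, n = 2), with limma adjusted p of 0.740 and 0.871. In the other direction, AT3G61360 had 4.97 ± 0.04 (SD, n = 3) in Columbia and 5.44 ± 0.01 (SD, n = 2) in Landsberg erecta (limma adjusted p = 0.740). AT1G06750 had the same value of 4.70 on the 3 Columbia arrays and 4.90 and 4.88 on the Landsberg erecta arrays (limma adjusted p = 0.278), and its other probe set held 1 value on all arrays. AT1G24600 had a difference of -0.19 with a 95% interval from -0.23 to -0.15 (limma adjusted p = 0.871).

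Arrays of the same ecotype were not consistently closer to each other than arrays of different ecotypes. The Landsberg erecta pair had the fewest probe sets at least 2-fold apart, 100, whereas the 3 Columbia pairs had 254, 489 and 636 and the 6 pairs between ecotypes had 157 to 463. By the median absolute difference, Landsberg erecta replicate 1 lay closer to each Columbia array (0.11, 0.11 and 0.13) than to Landsberg erecta replicate 2 (0.14). The 4 pairs that included Columbia replicate 3 had more such probe sets than any other pair.

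**Figure D2:**
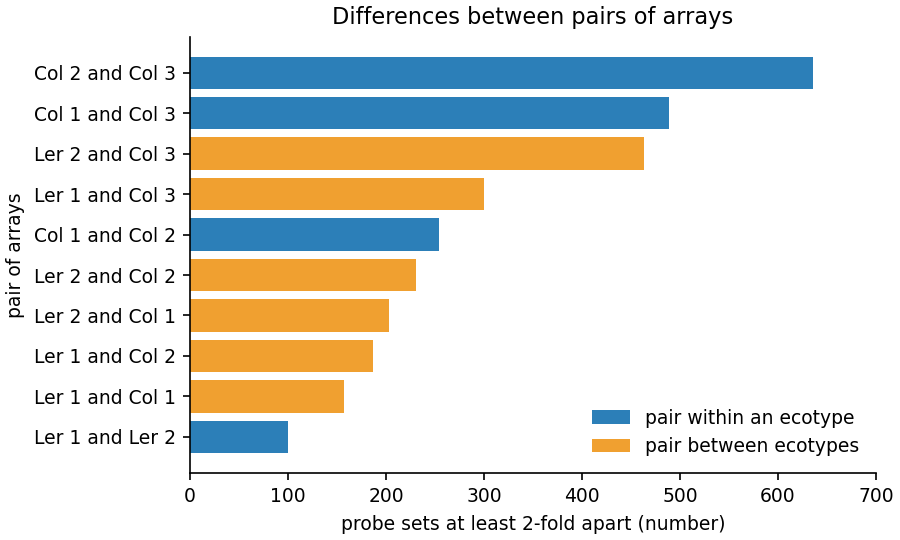
Number of probe sets at least 2-fold apart in each of the 10 pairs of arrays, with pairs within an ecotype in blue and pairs between ecotypes in orange (Col, Columbia; Ler, Landsberg erecta; the digit is the replicate). The bars run from 100 for the Landsberg erecta pair to 636 for Columbia replicates 2 and 3.

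Genes of photosynthesis, used as markers of green tissue, were the single fixed list out of 21 with a measured member that differed between the ecotypes in the camera set test. As a list they were higher in Columbia, by a median of 0.17 over 6 measured genes (5 above 0 and 1 below; camera adjusted p = 0.00687), a call lost with an estimated correlation (adjusted p = 0.911 with an estimated correlation) and not made by fry (adjusted p = 0.743). Of 10000 random lists of matched mean expression, drawn after the data were seen, 92.9% had a lower median (0.03 in the middle), and 0.02% for the anthocyanin list. Random genes do not move together as members of a list do, so these shares describe these arrays only and overstate how unusual a list is. RCA, which encodes Rubisco activase, had log2 values of 14.55 ± 0.05 (SD, n = 3) in Columbia and 14.38 ± 0.02 (SD, n = 2) in Landsberg erecta, and LHCB4.1, a light-harvesting protein of photosystem II named after its values were seen, had 13.87 ± 0.02 (SD, n = 3) and 13.67 ± 0.12 (SD, n = 2). No member passed over all probe sets (0 in either direction) or adjusted over the list alone (0). The list call rested on Landsberg erecta replicate 2, on which 5 of the 6 genes had their lowest value: without that array the median difference was 0.056 and the camera adjusted p 0.949. The list also lost its call without the 50% of probe sets with the lowest means (camera adjusted p = 0.146). The same held with the replicate number as a block (camera adjusted p = 0.0908). The GAPDH control, whose 3 prime to 5 prime ratio reads RNA integrity and labelling, differed along with the ecotypes, with a log2 ratio of 0.93 ± 0.04 (SD, n = 3) in Columbia and 1.24 ± 0.02 (SD, n = 2) in Landsberg erecta (exact permutation test, two-sided p = 0.1, the smallest that 10 splits allow). The corresponding ubiquitin ratio was 0.85 ± 0.11 (SD, n = 3) and 0.87 ± 0.03 (SD, n = 2; exact permutation test, two-sided p = 0.9). The 25S ribosomal RNA control had 8.01 ± 0.22 (SD, n = 3) in Columbia and 6.85 ± 0.44 (SD, n = 2) in Landsberg erecta, a difference of 1.17 (exact permutation test, two-sided p = 0.1), so a sign of RNA input or quality also moved with the ecotypes. Array medians differed by -0.02 (exact permutation test, two-sided p = 0.5).

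**Figure D3:**
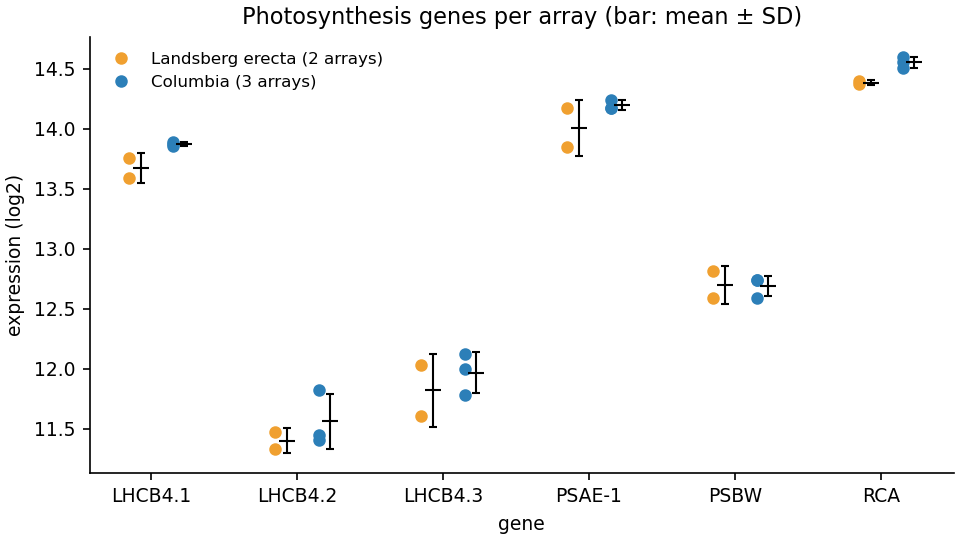
Log2 expression of the 6 measured photosynthesis genes on each array, with points for single arrays and bars for the mean ± SD of Landsberg erecta (orange, 2 arrays) and Columbia (blue, 3 arrays). RCA and LHCB4.1 show no overlap between the ecotypes, with means of 14.55 against 14.38 and 13.87 against 13.67.

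Genes of carbon metabolism were not called between the ecotypes by the set test with all arrays. The oxidative pentose phosphate pathway, which supplies NADPH and ribose phosphate, was represented by 3 genes of 6-phosphogluconate dehydrogenase, with a median difference of 0.01 (camera adjusted p = 0.869) and members between -0.08 and 0.07. AT1G64190 had 10.30 ± 0.09 (SD, n = 3) in Columbia and 10.23 ± 0.02 (SD, n = 2) in Landsberg erecta, with a 95% interval of the difference from -0.12 to 0.26, which excludes a 2-fold change. All 4 measured genes of the non-oxidative pentose phosphate pathway had higher means in Columbia, by a median of 0.10 (camera adjusted p = 0.215). All 4 were lowest on Landsberg erecta replicate 2. On replicate 1 the list median was 7.93, above the 7.84, 7.87 and 7.92 of Columbia replicates 1 to 3. The list passed without Landsberg erecta replicate 1 (camera adjusted p = 0.0111) and with the replicate number as a block (camera adjusted p = 0.0171), and not with an estimated correlation in these settings (adjusted p = 0.829 and 0.993) or over all arrays (0.911). AT1G12230 of this list had 9.22 ± 0.13 (SD, n = 3) and 8.96 ± 0.09 (SD, n = 2). Starch and sucrose metabolism had 3 of 5 members above 0 and a median of 0.03 (camera adjusted p = 0.976; its mean was also above 0 while the test pointed down). ATSPS4F, a sucrose phosphate synthase gene, had 5.77 ± 0.19 (SD, n = 3) and 6.13 ± 0.16 (SD, n = 2). No member of these 3 lists passed over all probe sets or adjusted over the list alone.

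Anthocyanin and flavonoid genes had lower means in Columbia for all 5 measured members, by a median of -0.41, and the list did not pass (camera adjusted p = 0.215; adjusted p = 0.911 with an estimated correlation). DFR, which encodes dihydroflavonol reductase, had values of 4.02, 4.86 and 4.02 on the Columbia arrays and 4.70 and 5.53 on the Landsberg erecta arrays, so that the difference of -0.81 had a 95% interval from -2.16 to 0.53. The list passed when array medians were equalized (camera adjusted p = 0.0381), without Columbia replicate 2 (camera adjusted p = 0.00122) and with the replicate number as a block (camera adjusted p = 0.00826). With an estimated correlation it passed in none of these settings (adjusted p = 0.873, 0.939 and 0.993). No member passed over all probe sets or adjusted over the list alone.

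Hormone, meristem and cell cycle lists also gave no call with all arrays. The cytokinin-induced type-A response regulators were represented by 2 genes with a median difference of -0.31 (camera adjusted p = 0.410), and ARR15 had 6.15 ± 0.08 (SD, n = 3) in Columbia and 6.34 ± 0.25 (SD, n = 2) in Landsberg erecta. Of 4 Aux/IAA genes, which encode repressors of auxin response, 2 held 1 value on all arrays (camera adjusted p = 0.781), and IAA30 had 4.03 ± 0.02 (SD, n = 3) and 4.05 ± 0.05 (SD, n = 2). The 3 gibberellin receptor genes had a median difference of 0.09 and a mean just under 0 (camera adjusted p = 0.976), and GID1B had 2.38 ± 0.09 (SD, n = 3) and 2.81 ± 0.37 (SD, n = 2). Both measured genes of shoot and axillary meristems, among them LAS, a regulator of axillary meristem formation, sat at the shared minimum of 2.15 on all 5 arrays (camera adjusted p = 0.976), as did UFO, the single measured gene of floral meristem and organ identity (camera adjusted p = 0.976). The 2 flowering time genes had a median difference of -0.22 (camera adjusted p = 0.784), with GI, a gene of the circadian clock and of photoperiodic flowering, at 7.85 ± 0.61 (SD, n = 3) and 8.25 ± 0.59 (SD, n = 2). Genes of mitosis and S phase had a median difference of -0.02 over 3 members (camera adjusted p = 0.838). They passed, lower in Columbia, without Columbia replicate 1 (camera adjusted p = 0.0188; adjusted p = 0.819 with an estimated correlation). AUR2, an Aurora kinase gene, had 7.82 ± 0.20 (SD, n = 3) and 7.93 ± 0.11 (SD, n = 2). SIM, the measured endocycle regulator, had 8.42 ± 0.39 (SD, n = 3) and 8.28 ± 0.19 (SD, n = 2; camera adjusted p = 0.838).

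Defence and wound lists gave no call between the ecotypes either. The 3 measured jasmonate genes had a median difference of -0.14 (camera adjusted p = 0.215), and THI2.1, a jasmonate-induced thionin gene, had 2.65 ± 0.18 (SD, n = 3) in Columbia and 2.97 ± 0.16 (SD, n = 2) in Landsberg erecta. Among 4 genes of the rapid wound and touch response, STZ, a zinc finger gene, had 2.21 ± 0.11 (SD, n = 3) in Columbia and 2.15 on both Landsberg erecta arrays (camera adjusted p = 0.838 for the list). SAG101, the measured gene of salicylate defence, had 2.78 ± 0.02 (SD, n = 3) in Columbia and 2.77 on both Landsberg erecta arrays (camera adjusted p = 0.781). Of 24 NBS-LRR resistance genes, a family rich in differences between ecotypes, 14 held 1 value on all arrays, 2 had a higher mean in Columbia and 8 in Landsberg erecta, with differences between -0.32 and 0.21 (camera adjusted p = 0.432), and AT5G46450 had 2.44 on the Columbia arrays and 2.44 and 3.08 on the Landsberg erecta arrays. Glucosinolate synthesis had 3 of 4 measured genes above 0, with a median of 0.05 (camera adjusted p = 0.838), and UGT74B1, a glucosyltransferase of that pathway, had 9.98 ± 0.33 (SD, n = 3) and 9.77 ± 0.11 (SD, n = 2). AOP3, a glucosinolate gene that natural variation sets apart between these ecotypes and that was chosen to check the labels, had the identical value of 2.27 on all 5 arrays, near the shared minimum, so it did not separate the labels. G6PD1, ERECTA, FLC and ESP, chosen beforehand along with it, had no probe set named through the table used here and were not analysed here.

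Markers of other tissues varied between arrays of an ecotype. GUT2, a gene of xylan synthesis in secondary walls and the measured marker of stem tissue, had 6.98 ± 1.24 (SD, n = 3) in Columbia and 7.85 ± 0.24 (SD, n = 2) in Landsberg erecta (camera adjusted p = 0.692). AMS, a regulator of tapetum development and the measured marker of anthers, had 6.07 ± 0.98 (SD, n = 3) and 6.46 ± 0.70 (SD, n = 2; camera adjusted p = 0.838). The 6 cytosolic ribosomal protein genes had a median difference of -0.06 (camera adjusted p = 0.629). They also passed, lower in Columbia, without Columbia replicate 1 (camera adjusted p = 0.0188; adjusted p = 0.819 with an estimated correlation). PGY1 had 12.82 ± 0.05 (SD, n = 3) and 12.93 ± 0.04 (SD, n = 2). In none of the 21 lists did a member pass over all probe sets or adjusted over the list alone. Cytokinin synthesis and breakdown, auxin transport, strigolactone and bud dormancy, and glucosinolate hydrolysis had 0 measured genes each.

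**Figure D4:**
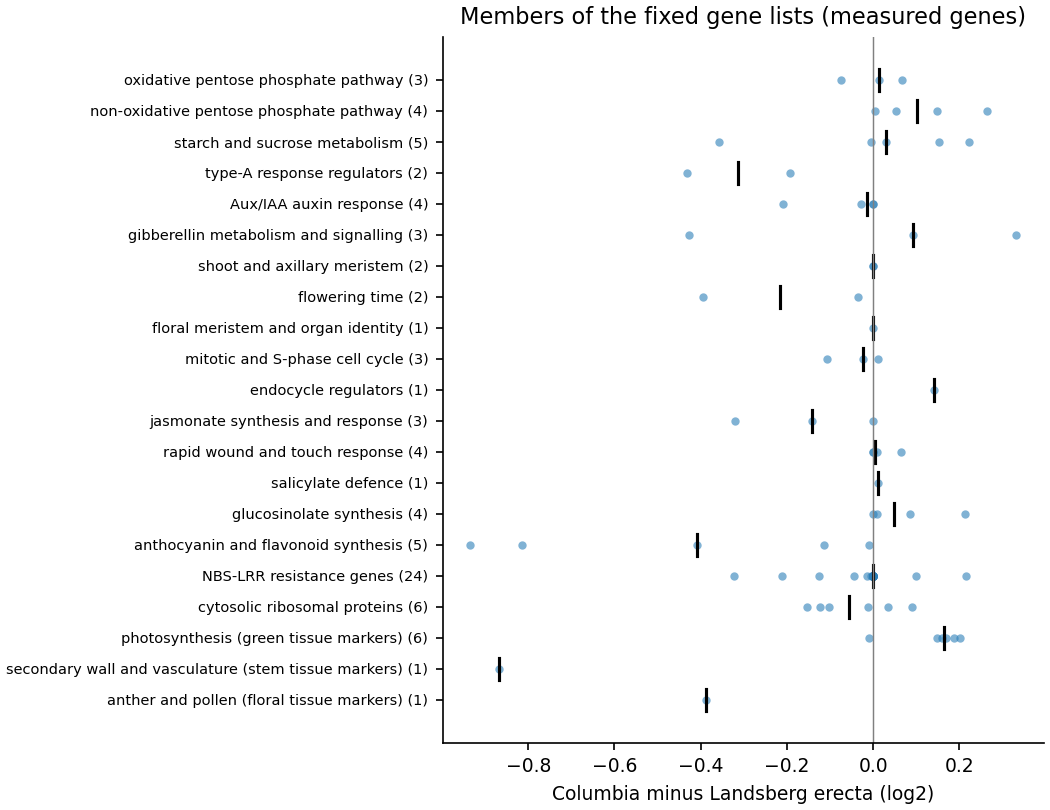
Difference between the ecotypes (Columbia minus Landsberg erecta, log2) of each measured member of the 21 fixed lists with at least 1 measured gene, with a point per gene, a black bar at the list's median and the number of measured genes in brackets. Photosynthesis has a median of 0.17 and the anthocyanin list one of -0.41.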

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

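The numbers of probe sets higher in Columbia and in Landsberg erecta stayed at 0 under quantile normalization, equal array medians, both filters, eBayes with a trend or robust, array weights, a 2-fold minimum, an adjusted p under 0.10, without probe sets that bind several genes, and in the fits added after the data were seen. At an unadjusted p under 0.05 they were 265 and 141. With single arrays left out they ranged from 0 to 356 and from 0 to 658; the calls came only where 1 Landsberg erecta array remained, 1014 without replicate 1 and 935 without replicate 2, with 355 probe sets in both, and 64.1% and 75.2% of them had 3 identical Columbia values. The number of fixed lists that differed was 1. It was 2 with equal array medians, 0 without the 50% of probe sets with the lowest means, 4 at an unadjusted p under 0.05, 0 with an estimated correlation (0 also, as added after the data were seen, together with equal array medians, the replicate block or any left-out array) and 0 with fry; with single arrays left out it ranged from 0 to 3. For all of these but the left-out arrays the cause was not tested. The difference of the array medians ranged from -0.0503 to 0.0071 with single arrays left out. The labels do not say that the replicate numbers pair arrays. Deviations from the group means correlated at -0.03 for replicate 1 and 0.08 for replicate 2, across probe sets, which gave little sign of a pairing. The deviations of the 2 Landsberg erecta arrays mirror each other, so these values are not independent. A pairing in growth or handling is not excluded by them. With the replicate block, no probe set was called (0 and 0) and 2 lists were, the anthocyanin and the non-oxidative pentose phosphate lists, while the photosynthesis list was not. The alternatives with other pseudocounts were not run, since the values were already on the log2 scale. Over named genes and the photosynthesis list, 503 values under an alternative kept their side of the threshold and moved by less than the spread between arrays or kept their call, 15 moved by more, 11 gained a call and 3 lost one, and none changed sign past the threshold. The lost calls counted here leave out camera with an estimated correlation and fry, neither of which called the photosynthesis list (adjusted p = 0.911 and 0.743). Signal over background limits what can be read: 24.4% to 25.2% of each array sat at the shared minimum.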

Other observations

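The tests in this part were chosen after the data were seen. Exceptions are AOP3 as a label check and the ecotype comparison at an unadjusted p under 0.05, both fixed beforehand. Some genes outside the fixed lists differed between single arrays. Columbia replicate 1 stood at least 2-fold below all other arrays for 45 probe sets; of these, picked after their values were seen and not tested as a group, IRX15-L, which acts in xylan synthesis, was at 5.02 there and at 7.09 to 8.83 on the other arrays, XTH19, a xyloglucan transferase gene, at 4.06 against 6.01 to 6.84, and PME61, a pectin methylesterase gene, at 6.25 against 7.91 to 9.37. Columbia replicate 3 stood at least 2-fold above all other arrays for 95 probe sets and below them for 87, the most of any array. LTI30, a dehydrin gene, was at 9.13 there and at 5.38 to 6.71 elsewhere, while EMS1, a receptor kinase gene of anther development, was at 3.34 there and at 4.93 to 5.74 elsewhere.

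Heat shock genes had higher means in Columbia for 5 of 6 measured members, and the list, added after the data were seen, passed camera over the 4 added lists (adjusted p = 0.0301) but not with an estimated correlation (adjusted p = 0.706 with an estimated correlation). The list medians were 5.56 and 5.65 on Columbia replicates 1 and 2 but 4.75 on replicate 3, below the 4.88 of Landsberg erecta replicate 1. AT1G53540, a small heat shock protein gene, had 5.32 ± 0.53 (SD, n = 3) in Columbia and 4.14 ± 0.68 (SD, n = 2) in Landsberg erecta, without overlap. Plastid-encoded genes were lower in Columbia as a list (51 of 69 below 0, median -0.13, camera adjusted p = 0.000354), a call also lost with an estimated correlation (adjusted p = 0.788 with an estimated correlation). The Landsberg erecta arrays went opposite ways: 53 of the 69 genes were highest on replicate 2, while 36 were lowest on replicate 1 (median 10.37, against 10.42 to 10.69 on the Columbia arrays). The clock list (3 genes) and the cold response list (4 genes) gave camera adjusted p of 0.437 and 0.912. The other named genes whose ecotypes did not overlap and whose means lay at least 2-fold apart were AT1G06260 and the plastid gene rpl14, higher in Columbia, and AT1G01320 and PPDK, higher in Landsberg erecta, with differences of 1.32, 1.09, -1.53 and -1.01. AT1G01320 was at 6.71 on Landsberg erecta replicate 2 and at 4.05 on replicate 1.

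The absence of a called difference between these ecotypes is the first pattern weighed. That too few arrays hid differences cannot be told apart from a true absence of them, since the 95% interval of 2335 varying probe sets reached 2-fold and smaller differences stay open throughout. The 4 pairs of arrays of 1 ecotype had 8, 27, 89 and 116 probe sets at least 4-fold apart. These counts argue against a removal of large differences between all arrays before deposit. They cannot decide about a step that removed differences between the ecotypes alone, since it would leave them unchanged. Flattening of small differences cannot be told apart from similarity. Of the probe sets with a mean above 5, 42.1% held the same value on at least 2 arrays, and the processing is not given. A candidate explanation is that arrays with both labels hold RNA of 1 ecotype: the 1556 probe sets without overlap were no more than in the other 9 splits of the arrays into 3 and 2 (1664 to 2286), a count made the deciding one after its values were seen, in place of gaps of at least 2-fold between the groups (0 probe sets, as in 4 of the 9), and other counts were low without being the lowest (8 without overlap and 2-fold apart against 3 to 103; 406 at an unadjusted p under 0.05 against 380 to 624), although the arrays labelled Landsberg erecta had the fewest probe sets 2-fold apart of any pair, 100, and AOP3, the label check that could be read, was at 2.27 on all arrays and decides nothing so near the minimum. A true similarity of these ecotypes in this tissue after clipping stays open and was not tested.

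Plastid-encoded genes differed between the Landsberg erecta arrays, with 62 of 69 higher on replicate 2 than on replicate 1, by a median of 0.50 ± 0.77 (SD over genes). For psaA, a gene of photosystem I, the values were 9.32 and 12.34, and the Columbia arrays had 10.42, 10.42 and 10.41. More green tissue on replicate 2 is argued against by the nuclear photosynthesis genes, whose median difference was -0.20 ± 0.16 (SD over 6 genes) in the opposite direction. A difference in RNA input or labelling may account for it, since 8 of 12 probe sets of spiked bacterial transcripts were higher on replicate 2 by at least 0.81 and 4 did not move by more than 0.004 (median over the 12 of 0.91 ± 0.67, SD over probe sets, against a median range of 0.19 over the Columbia arrays), while 18 probe sets of the hybridization controls moved little, by a median of 0.04 ± 0.08 (SD over probe sets); whether input and plastid transcripts share a cause cannot be told apart here. The 4 spike probe sets that did not move had low values on both arrays. Those of lys were at 2.15 to 2.69, near the shared minimum, and phe-3 was at 3.65. However, phe-5 and phe-M, at 2.77 and 3.13 on replicate 1, did rise. The 25S ribosomal RNA control moved in the opposite direction from the spikes, at 7.16 on replicate 1 and 6.53 on replicate 2. No other biological explanation was tested.

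Cold-regulated genes and clock outputs were lowest on Columbia replicate 2. COR27, a gene under cold and clock control, was at 2.50 there and at 6.79 to 8.10 on the other arrays, and AT4G33980, also called COR28, was at 3.13 against 4.77 to 6.81. Another time of day or temperature before the harvest of that sample cannot be told apart from other causes: all 7 measured members of the added clock and cold lists were lowest there, but both lists were written after these values were seen, and any cause of a shared drop would give this count. An array-wide disturbance left in the deposited values is argued against by the median absolute difference of Columbia replicate 2 from the other arrays. It was 0.117 on average, with 0.117 to 0.140 for the other 4 arrays. A shift in brightness that the processing took out would not show in this measure and is not excluded. The hybridization controls did shift a little, with 17 of 18 probe sets lowest on Columbia replicate 2. Their median was -0.21 ± 0.14 (SD over probe sets) from the mean of the other arrays, against -1.19 for the cold list and -2.17 for the clock list. That mean includes Columbia replicate 3, which widens the cold value. COR47 was at 11.07 on replicate 2 and at 11.21 to 11.95 elsewhere, and COR15B at 7.83 against 9.35 to 9.96. The cold genes were also highest on Columbia replicate 3, 4 of 4, and no biological explanation beyond this was tested.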
